A study of Homo sapiens with 12 samples.

How the data were processed

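Total RNA from THP-1 cells in 4 states was measured on 12 single-colour (Cy3) Agilent-format arrays, 3 per state. Per the submitters' processing notes, signals were extracted with Agilent Feature Extraction 9.1. The authors deposited normalized log2 values; the log2 scale was read from the range of the values, and the normalization method is not given in the sources used here. The deposited value table holds 120932 rows, of which 120864 are custom probes and 68 are control features. Separate deposited tables of M0, M1 and M2 held the same log2 values within 1e-08 in all 9 columns. A further table has 3 columns whose names match no sample's labels, and these 3 columns were not used.

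The 9 arrays of M0, M1 and M2 share a lowest value, and the 3 CM-sM2 arrays have another, at 1.514 to 1.515. Lower quartiles of the custom probes were 2.45 to 2.50 on the 9 arrays and 2.13 to 2.15 on the CM-sM2 arrays, and upper quartiles 7.22 to 7.23 and 7.17 to 7.18, while the medians overlapped. These sets therefore look normalized separately by the authors. Separate normalization is inferred from these values and is not stated in the sources used here. A test of CM-sM2 against the other groups had been chosen before the data were examined; it was not used for that reason, and CM-sM2 is described by values alone. Normalization and any difference in labelling or hybridization coincide with that group.

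Probes were kept where their value lay above the array's 30th percentile on at least 3 of the 12 arrays, which left 96330 custom probes and removed 24534. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend) with a mean for each of the 4 groups and 8 residual degrees of freedom. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the filtered probes within each comparison, and probes were called at an adjusted p under 0.05. The 4 GAPDH and PGK1 control probes and the control feature ETG09_35454 were added to the same fit. These 5 in 3 comparisons were also compared by exact two-sided permutation tests.

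No detection calls were used; a probe was taken as above background on an array where it exceeded the negative control probe of that array by more than 1 log2 unit, a margin chosen after the data were seen. Where a probe was not above background on any array of a group, the change is given as at least N-fold, from the mean of the brighter group against the mean of the higher of the probe's own value and that limit on each array. The number of arrays limits the precision.

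The files do not pair probe IDs with genes. The planned counts of genes, the 24 gene lists of macrophage states and other cell types, the marker genes and a split into coding and non-coding RNAs were therefore not tested, and no list has a result here. The rule for named items, fixed before the data were examined, gave in this case at most 2 probes that rose and 2 that fell per comparison: those with the largest log2 difference among called probes whose 3 arrays of one group all lay beyond the 3 of the other. The control probes named were chosen after their values were seen.

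Distances between groups are mean squared differences of group means less the variance of those means. Values expected from shared M0 arrays came from 20 simulations of unchanged groups with each probe's residual variance, pooled over the 4 groups. Only the spread of the M0 arrays makes up the shared part, so these values are approximate. Lists matched on mean signal were drawn 10000 times in bins 0.5 log2 units wide from probes not called in the same comparison. The replicate numbers in the labels were not taken as pairs: deviations of same-numbered arrays correlated between -0.080 and 0.088.

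The fit was tested on simulated data, with 200 of 96330 probes changed on a background of the real means and residual variances. In M1 against M0 it recovered 58.2% of probes changed by 2 log2 units, 26.9% of those changed by 1 and 3.03% of those changed by 0.5, with 5 false calls among 64. In M2 against M0 it recovered 56.7%, 22.4% and 1.51%, with 4 false calls among 58. In M1 against M2 it recovered 47.8%, 23.9% and 1.51%, with 4 false calls among 53. A criterion of over 80% recovery at a change of 2 log2 units, set before this test was run, was met in 0 of 3 comparisons. It was replaced, after this was seen, by limits of 10% on the bias of the estimates at that change and 15% on the share of false calls, which were met in 3 of 3. Many changed probes are thus missed when few probes change, and the share of false calls in these runs was between 6.90% and 7.81%.

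Alternatives were other filters, 75th percentile centring, quantile normalization, a trend with robust estimation, the arrays of the compared groups alone, the replicate number as a block, a 2-fold minimum, limma's treat against 1.2-fold, and leaving out each array. Figures were drawn with matplotlib 3.10.9.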

Results

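THP-1 is a human monocytic leukaemia cell line that takes on macrophage features when it is treated with the phorbol ester PMA. RNA from 4 states of these cells was hybridised to a single-colour array designed for human long non-coding RNAs, in 3 samples per state and 12 arrays in all. The M0 cells had received 50 ng/ml PMA for 48 h. M1 cells were M0 cells given 100 ng/ml of the bacterial product LPS and 20 ng/ml of the cytokine interferon-γ for 48 h, and M2 cells were M0 cells given 20 ng/ml interleukin-4 for 48 h. CM-sM2 cells were M0 cells given 30% culture medium of gastric cancer cells, for a time the labels do not give. The series asks which RNAs go with each of these macrophage states. The files do not pair probe IDs with genes, so results are for probes, and several probes may measure one transcript.

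Between 61.4% and 65.7% of the 120864 custom probes lay more than 1 log2 unit above the negative control probe on the M0, M1 and M2 arrays. On the CM-sM2 arrays the share was between 67.2% and 70.4%. The lowest value was 1.96 on each of the 9 M0, M1 and M2 arrays and 1.514 to 1.515 on the CM-sM2 arrays. The CM-sM2 arrays therefore appear to have been normalized apart from the rest. Over the 96330 probes that passed the filter, arrays of M0 correlated at 0.981 on average, those of M1 at 0.977, those of M2 at 0.982 and those of CM-sM2 at 0.976. Mean correlation was 0.976 between M0 and M2, 0.954 between M0 and M1, and 0.952 between M1 and M2. The CM-sM2 arrays correlated with M0 at 0.915, with M2 at 0.916 and with M1 at 0.890. These correlations are across probes, which are not independent replicates. The labels do not say whether the 3 samples of a state came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

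**Figure D1:**
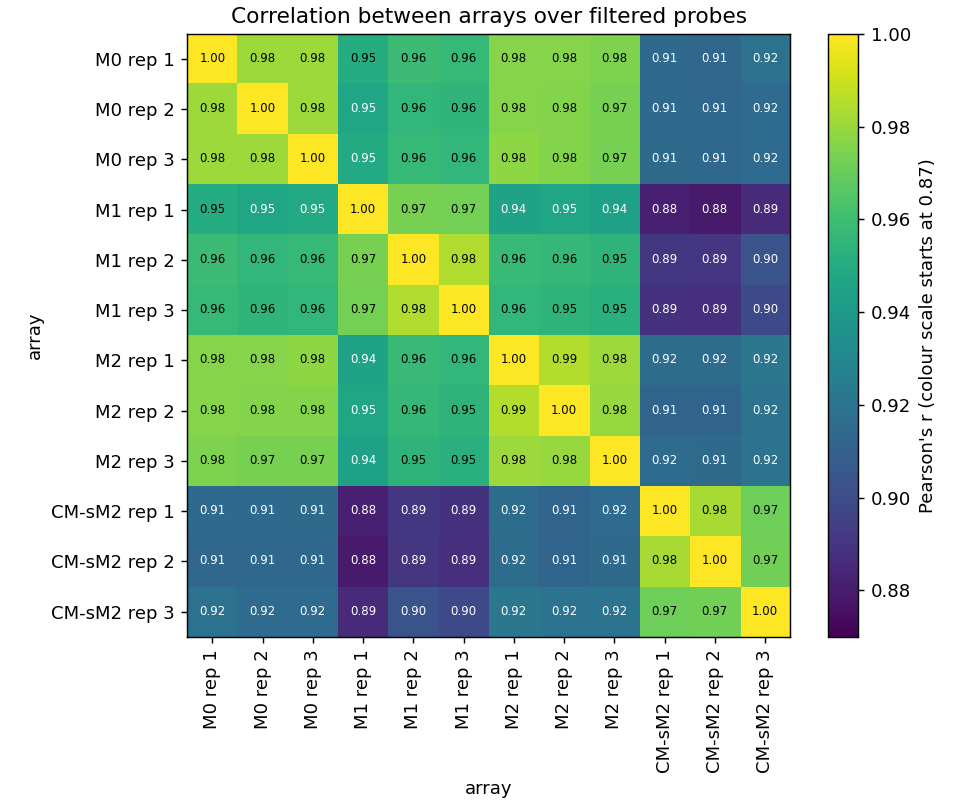
Pearson's r between each pair of the 12 arrays over the 96330 filtered probes, on a colour scale that starts at 0.87. The M0 and M2 arrays form the closest pair of groups, at a mean of 0.976, and the CM-sM2 arrays stand apart, at 0.890 to 0.916 on average against the other groups.

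The comparison of M1 with M0 addresses the response to LPS and interferon-γ. The labels do not say whether M0 cells were kept in culture for the further 48 h, so differences of M1 and of M2 from M0 may hold time in culture as well as the stimulus. M1 cells differed from M0 cells in 26755 of 96330 probes (27.8%) at an adjusted p under 0.05 by limma. Of these, 11697 rose and 15058 fell. At least 2-fold changes made up 11224 of the calls, 4339 higher and 6885 lower in M1. Changes of at least 16-fold were found for 100 probes that rose and 134 that fell. Some probes were more than 1 log2 unit above the negative control on all 3 arrays of one state and on none of the other: 386 such called probes were seen in M1 alone and 793 in M0 alone.

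Probe CUST_127454_PI430048170 rose from a log2 signal of 5.42 ± 0.113 in M0 to 16.12 ± 0.070 in M1 (SD, n = 3). The log2 difference was 10.69 ± 0.152 (SE), a 1654-fold change, with a limma adjusted p of 1.33e-09. CUST_130770_PI430048170 rose by 9.53 ± 0.261, from 4.14 ± 0.210 to 13.67 ± 0.206. On the other side, CUST_141497_PI430048170 lay at 10.07 ± 0.103 in M0 and was not above background on any M1 array, which makes it at least 116-fold lower in M1 (limma adjusted p = 6.21e-08). CUST_44314_PI430048170 fell by 6.45 ± 0.187, from 9.67 ± 0.124 in M0 to 3.22 ± 0.429 in M1, where 2 of the 3 arrays were above background.

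GAPDH and PGK1, genes of glycolytic enzymes, are measured by named control probes on the array, with a pair of probes for each gene. Both GAPDH probes read lower in M1. Human-GAPDH_5 read 12.82 ± 0.030 in M0 and 12.25 ± 0.072 in M1 (SD, n = 3), a log2 difference of -0.56 ± 0.097 (limma adjusted p = 0.00158). Human-GAPDH_3 differed by -0.32 ± 0.096 (limma adjusted p = 0.0329), and its call was lost without M0 replicate 1, 2 or 3 or M1 replicate 2 or 3, at adjusted p values of 0.0781 to 0.0995. PGK1 gave -0.45 ± 0.131 on Human-PGK1_5 (limma adjusted p = 0.0286, lost without the same arrays, each in turn, at 0.0645 to 0.0991) and -0.08 ± 0.114 on Human-PGK1_3 (limma adjusted p = 0.660). All 4 probes were lower in M1 under the deposited scaling, 75th percentile centring and quantile normalization. The exact two-sided permutation test of 3 arrays against 3 cannot go below p = 0.1, which both GAPDH probes and Human-PGK1_5 reached. The gap between the paired probes widened from M0 to M1 by 0.24 for GAPDH and by 0.36 for PGK1 (exact permutation p = 0.1 each). From M0 to M2 it widened by 0.16 for PGK1 (exact permutation p = 0.1) and by 0.05 for GAPDH (exact permutation p = 0.4). What the endings 3 and 5 mean is not stated. Human-GAPDH_5 and Human-PGK1_5 fell more in M1 than their partners, so these values do not settle whether or how far either gene fell.

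**Figure D2:**
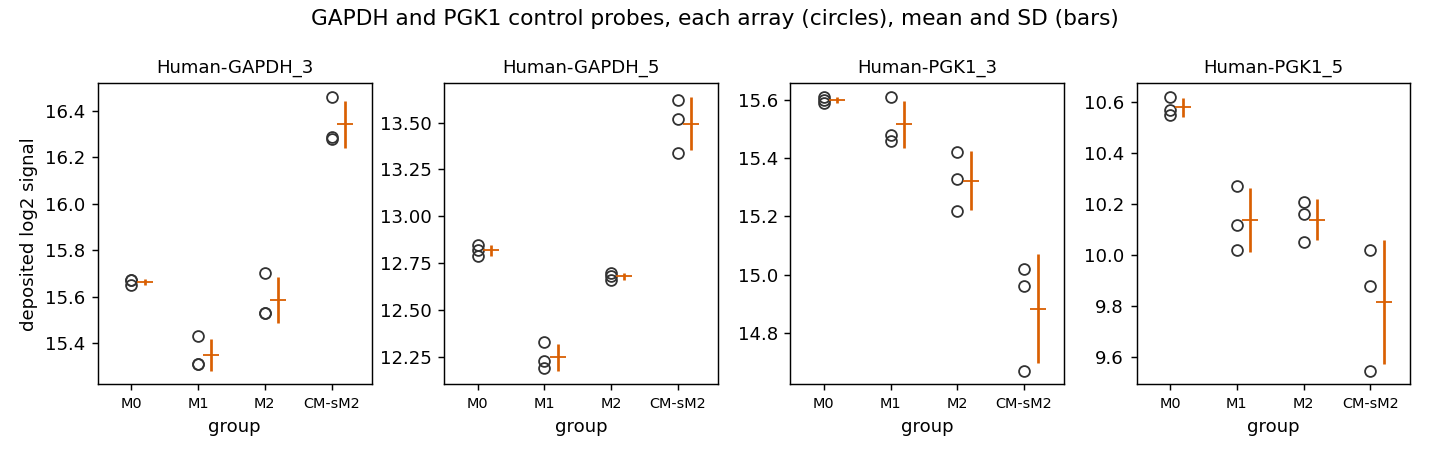
Deposited log2 signal of the GAPDH and PGK1 control probes on each array (circles), with group mean and SD (bars, n = 3); each panel has its own axis, which does not start at 0. Human-GAPDH_5 falls from 12.82 in M0 to 12.25 in M1, and the CM-sM2 values come from arrays that look normalized apart.

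The comparison of M2 with M0 addresses interleukin-4, with the same limit on time in culture. M2 cells differed from M0 cells in 5084 probes (5.28%) by limma at an adjusted p under 0.05, of which 2371 rose and 2713 fell. At least 2-fold changes made up 1738 of these, and there the balance was the other way, with 1060 higher and 678 lower in M2. At least 16-fold changes were 42 higher and 1 lower. A total of 183 called probes were above background on all 3 M2 arrays and on no M0 array, and 75 the other way round. Leaving out any array of the pair of groups lowered the count to between 2928 (without M0 replicate 2) and 3207 (without M0 replicate 3), with 2990 without M0 replicate 1, 3044 without M2 replicate 1, 3029 without M2 replicate 2 and 3200 without M2 replicate 3. The share of all M2 calls that were higher grew with each of these arrays left out, from 46.6% with all arrays. It was 49.6% without M0 replicate 1, 53.1% without M0 replicate 2 and 53.3% without M0 replicate 3. Without M2 replicate 1 it was 49.97%, without M2 replicate 2 52.7% and without M2 replicate 3 50.6%. The change is thus not tied to a particular array, and whether it comes with the lower number of calls was not tested.

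CUST_137614_PI430048170 was not above background on any M0 array and read 8.66 ± 0.075 in M2 (SD, n = 3), at least 43.9-fold higher (limma adjusted p = 3.49e-06). CUST_133862_PI430048170 was likewise at background in M0 and reached 9.24 ± 0.396 in M2, at least 65.8-fold higher (limma adjusted p = 0.000267). Both probes had low mean signals in M1, at 2.53 and 2.32. CUST_126853_PI430048170 read 6.62 ± 0.036 in M0 and was not above background on any M2 array, at least 11.1-fold lower (limma adjusted p = 3.33e-07). Its mean signal was low in M1 too, at 2.41. CUST_137537_PI430048170 fell by 3.84 ± 0.157, from 7.17 ± 0.075 in M0 to 3.33 ± 0.307 in M2, where 1 of 3 arrays was above background, while it read 8.01 ± 0.032 in M1. None of the 4 GAPDH and PGK1 probes was called in M2. Their log2 differences from M0 lay between -0.44 and -0.08, with limma adjusted p values of 0.0990 to 0.760. Human-PGK1_5 differed by -0.44 ± 0.131 (SE) in M2, close to its -0.45 ± 0.131 in M1, so its call in M1 alone does not separate the states. Human-GAPDH_5, Human-PGK1_3 and Human-PGK1_5 reached the lowest exact permutation p of 0.1 in M2 too.

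M1 and M2 cells were compared with each other directly. They differed in 27284 probes (28.3%) by limma at an adjusted p under 0.05, with 12356 higher and 14928 lower in M1, and 12118 of the calls were at least 2-fold. CUST_127454_PI430048170 had the largest log2 difference among the called probes, at 16.12 ± 0.070 in M1 against 3.58 ± 0.304 in M2 (SD, n = 3), a log2 difference of 12.53 ± 0.152 (SE; limma adjusted p = 2e-10). CUST_144769_PI430048170 was higher in M1 by 10.10 ± 0.125, at 16.28 ± 0.044 against 6.18 ± 0.206. CUST_141352_PI430048170 read 11.71 ± 0.234 in M2 and was not above background on any M1 array, at least 361-fold lower in M1. CUST_144639_PI430048170 was lower in M1 by a log2 difference of -8.87 ± 0.311, at 6.16 ± 0.350 against 15.04 ± 0.115. Human-GAPDH_5 was lower in M1 than in M2 by a log2 difference of -0.43 ± 0.097 (limma adjusted p = 0.00752). The remaining GAPDH and PGK1 probes were not called. Human-GAPDH_3 differed by -0.24, Human-PGK1_3 by 0.19 and Human-PGK1_5 by -0.0088 (limma adjusted p = 0.102, 0.259 and 0.974).

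**Figure D3:**
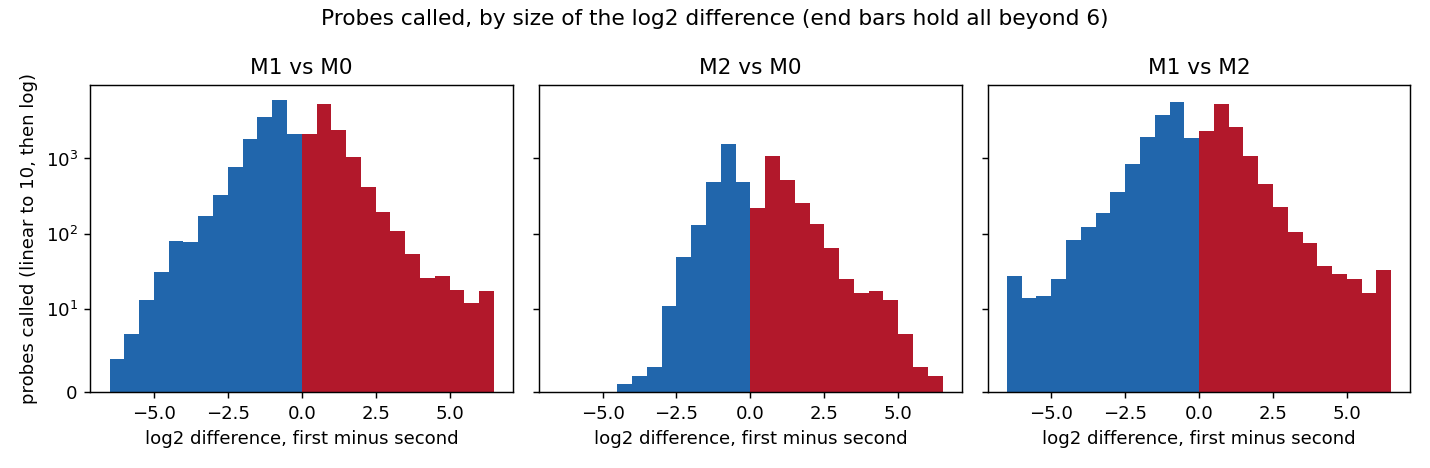
Number of probes called by limma at an adjusted p under 0.05 (vertical axis, linear to 10 and logarithmic above) by log2 difference (horizontal axis, bins 0.5 wide) in each comparison. Bars to the right are probes higher in the first group; M1 against M0 holds 26755 calls and M2 against M0 holds 5084.

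The probes that changed in M1 and in M2 overlapped in both the same and opposite directions. Of the probes called in M2 against M0, 2025 (39.8%) were also called in the same direction in M1 against M0 and 1371 (27.0%) in the opposite direction. In the same direction, 802 probes rose in both states, where independent lists would share 287.9, and 1223 fell in both, where independent lists would share 424.1. In opposite directions, 723 rose in M1 and fell in M2 (329.4 for independent lists) and 648 fell in M1 and rose in M2 (370.6). Simulated unchanged groups against the same M0 arrays shared a mean of 0 calls, but such groups give few calls by construction, so this sets no expected value for the overlap. Part of the excess over independent lists in the same direction may come from the shared M0 arrays or, if M0 cells were harvested earlier, from time in culture. Independent lists also take no account of signal level, and brighter probes were called more often in both comparisons. The excess in either direction may hold that too, which was not tested. Across probes the M1 and M2 log2 differences had a covariance of 0.092. Unchanged groups sharing M0, simulated with a spread pooled over all 4 groups, gave an approximate 0.070. The correlation of the M1 and M2 differences was 0.24. The simulated correlation of 0.50 follows by construction from unchanged groups that share M0, so it sets no expected value for groups that changed.

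The cells given gastric cancer cell medium are described in the title as similar to M2, and were set beside each other state. From their lowest values and quartiles these arrays look normalized apart, and the difference between CM-sM2 and any other state may then hold the normalization too. No test was run for it and no probe is called. Group means of CM-sM2 and M0 differed at least 2-fold in 26039 of 96330 probes (27.0%), 11964 higher and 14075 lower in CM-sM2. After quantile normalization of all 12 arrays together the number was 24859, with 13466 higher and 11393 lower, so the more frequent direction depended on the scaling. For CM-sM2 against M2 the number was 24819 (25.8%), and against M1 it was 34535 (35.9%). The same count without a test was 4662 for M2 against M0 and 14260 for M1 against M0. E1A control probes, which do not measure human genes, differed between CM-sM2 and M0 by a median log2 difference of -0.91 over the 9 of 10 whose mean log2 signal was above 5, against -0.12 in M2 and -0.03 in M1. Over all 10 the CM-sM2 median was -0.84.

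The mean squared log2 difference between group means, less the part due to spread between arrays, was 0.11 for M2 against M0, 0.49 for M1 against M0 and 0.54 for M1 against M2. For CM-sM2 it was 1.27 against M2, 1.29 against M0 and 1.76 against M1. Leaving out each array in turn gave 1.21 to 1.39 for CM-sM2 against M2 and 1.23 to 1.38 for CM-sM2 against M0, so CM-sM2 was not separated in its distance to M2 and M0, and lay farther from M1, at 1.68 to 1.90.

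Probes called in M2 cells lay to the same side of matched probes in CM-sM2 cells. The 2371 probes called higher in M2 had a median log2 difference of 0.26 between CM-sM2 and M0 (0.20 to 0.30 over the 3 CM-sM2 arrays), against -0.10 for lists of uncalled probes matched on mean signal. The 2713 probes called lower in M2 had a median of -0.48 (-0.60 to -0.39), against -0.10 for matched lists. Both medians lay beyond all 10000 random lists. Among the probes named for M2 against M0, only CUST_126853_PI430048170 followed these medians. Lower in M2, it read 1.79 ± 0.069 in CM-sM2 (SD, n = 3), against 6.62 in M0. CUST_137614_PI430048170 and CUST_133862_PI430048170, higher in M2, read 1.94 ± 0.351 and 2.43 ± 1.51 in CM-sM2, against 2.34 and 3.01 in M0. CUST_137537_PI430048170, lower in M2, read 7.84 ± 0.190 in CM-sM2, against 7.17 in M0. CUST_141352_PI430048170 and CUST_144639_PI430048170, the probes named as lower in M1 than in M2, read 1.81 ± 0.0044 and 4.11 ± 0.720 in CM-sM2. They read 7.30 and 10.33 in M0 and 11.71 and 15.04 in M2, so in CM-sM2 they lay below both. In CM-sM2 57.8% of the probes called higher in M2 were above M0, where 45.1% of matched probes were, and 62.5% of those called lower in M2 were below M0, where 55.2% of matched probes were. Probes called higher in M1 had a median of -0.14, against -0.16 for matched lists, at the 94.2 percentile. That set kept no side of its matched probes: with quantile normalization it was at -0.06 against -0.10, at the 99.99 percentile, and with separate M0 arrays at -0.18 against -0.14. Probes called lower in M1 had a median of 0.08 (-0.08 to 0.16 over the 3 arrays), against -0.16, and so lay above matched probes in CM-sM2. That median was 0.16 without CM-sM2 replicate 3, 0.04 without CM-sM2 replicate 1 and 0.04 without CM-sM2 replicate 2. These medians share the M0 arrays with the calls; with calls from 2 M0 arrays and the difference taken from the remaining array, the medians were 0.20 and -0.61 for the M2 sets and 0.11 for probes called lower in M1. The percentiles describe these arrays and are not a test.

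**Figure D4:**
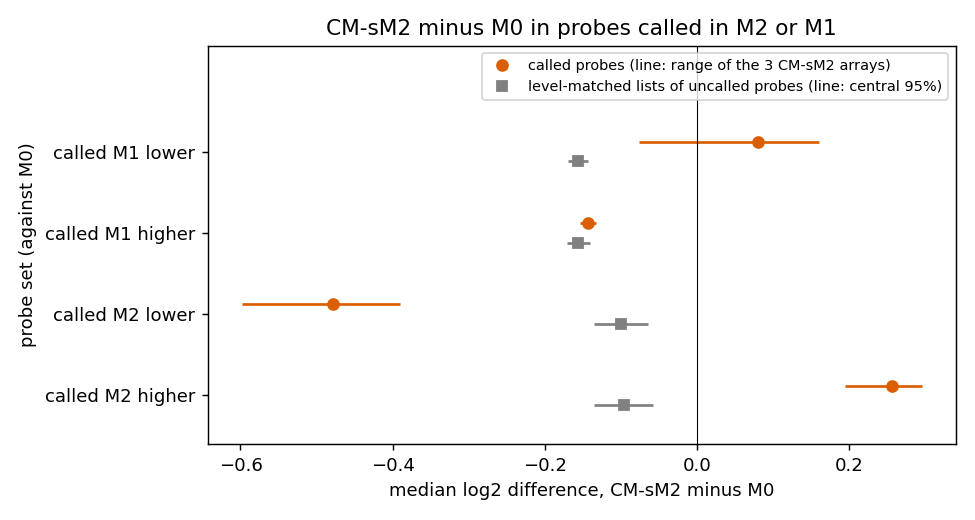
Median log2 difference of CM-sM2 minus M0 (horizontal axis) in probes called higher or lower in M2 or M1 (orange, with the range over the 3 CM-sM2 arrays), and in 10000 lists of uncalled probes matched on mean signal (grey, with their central range). Probes called higher in M2 sit at 0.26 and those called lower at -0.48, on arrays that look normalized apart from M0.

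Across all filtered probes, the CM-sM2 and M2 differences from M0 had a covariance of 0.129, against 0.070 simulated for unchanged groups that share M0. Their correlation was 0.22, and the simulated one of 0.50 again follows by construction and sets no expected value. With separate M0 arrays for each difference the covariance was 0.067, against 0.00039 simulated for unchanged groups with separate M0 arrays, and the correlation was 0.10, against 0.0018 simulated. For CM-sM2 and M1 the covariance was 0.067 with shared M0 arrays, against 0.070 simulated, and 0.0052 with separate ones, against 0.00039 simulated. The simulated 0.070 used a spread pooled over all 4 groups and not that of M0 alone, so 0.067 cannot be read as below it.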

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

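The test of the E1A control probes and that of joint normalization were chosen after the difference of the CM-sM2 arrays was seen. Groups of 3 were not tested for outlying arrays. CM-sM2 replicate 3 stood apart within its group, at correlations of 0.971 and 0.973 with replicates 1 and 2 against 0.983 between these.

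The control feature ETG09_35454, a row outside the custom probes that the report does not describe, gave signal in M1 above every M0 array: 9.79 ± 0.029 against 8.34 ± 0.202 (SD, n = 3), a log2 difference of 1.45 (limma adjusted p = 0.000299). It read 8.46 ± 0.187 in M2 and 2.43 ± 0.399 in CM-sM2, on arrays that look normalized apart.

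The CM-sM2 arrays stood far from the other 9. If separate normalization alone were the source, joint quantile normalization should bring the number of probes with 2-fold different means down to that of M2 against M0, but CM-sM2 against M0 still had 5.05 times as many. That argues against normalization of whole distributions as the whole source. A labelling or hybridization batch is a candidate explanation: the 9 of 10 E1A control probes with a mean log2 signal above 5, which do not measure human genes, differed between CM-sM2 and M0 by a median of -0.905, with array medians of -1.28 to -0.587, and by -0.857 after 75th percentile centring and -0.867 after quantile normalization. An effect of the cancer cell medium stays open and untested, since batch and normalization coincide with that state.

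M1 replicate 1 correlated less with M1 replicates 2 and 3 than these did with each other, and its dark corner and negative control signals were the highest among the M0, M1 and M2 arrays, at 3.10 and 2.35. A raised background could have set it apart, but its deviation from the other M1 arrays was 1.54 times theirs among the 17224 bright probes and 1.26 times theirs among the 42424 dim ones, where background should act most. A weaker or stronger response in that sample was tested by the slope of its deviation on the effect of the other M1 arrays. Over the 26755 probes called in M1 the slope was 0.00256, against -0.0417 for replicate 2 and -0.0251 for replicate 3. The mean of the other arrays enters both sides, which lowers each slope, and the calls included replicate 1. In log2 units replicate 1 deviated by 0.939 among dim probes, against 0.739 and 0.753 for replicates 2 and 3. Among bright probes it deviated by 0.263, against 0.176 and 0.164. Dim probes varied more on every M1 array, which holds their ratio down. The first test thus argues only against a raised background as the whole source, and cannot exclude it as a part. The slope argues only against a large difference in response. What sets the array apart stays open.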

How the results depend on the processing

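The fit on the 9 arrays of M0, M1 and M2, the filter on the negative control and the split of the M0 arrays were chosen after seeing the data. Calls stayed within 1.5 times the reported count under the other filters, scalings, trend, block, and fits on the compared groups alone or on the 9 arrays. They moved with a 2-fold minimum (11224 in M1 against M0, 1738 in M2 against M0, 12118 in M1 against M2) and with treat (16522, 1988 and 17422), by construction; the share higher in M2 went from 46.6% to 61.0% and 56.9%. Leaving out each array gave 21704 to 24862, 2928 to 3207 and 22692 to 24481, with fewer arrays per group. The count of M2 against M0 thus moved beyond 1.5 times with every array left out. Of its reported calls 54.3% to 59.4% were kept, against 68.0% with the replicate number as a block. With the replicate number as a block there were 24526, 3560 and 25065 calls; 3 of 12 arrays correlated best with an array of their own number, so the numbers are not taken as pairs. On the 9 arrays of M0, M1 and M2 there were 30396, 6669 and 30630 calls.

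All 96 alternative values of the 12 probe differences kept their direction and call. These 12 were picked from the same arrays as the largest called differences, so their stability says little about other probes. Of 120 for 5 control probes (ETG09_35454 included), 10 lost the call (Human-GAPDH_3 and Human-PGK1_5 in M1 against M0) and 4 changed sign: Human-PGK1_5 in M1 against M2, uncalled at -0.0088, was 0.0057 with quantile normalization and -0.074 to 0.049 with an array left out.

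The counts of 2-fold different means for CM-sM2 stayed within 1.5 times under each filter, scaling and array left out. No fit with the replicate number as a block was run for CM-sM2, for which no test was used. The correlation of CM-sM2 with M2 differences was 0.195 to 0.263 with an array left out and 0.105 with separate M0 arrays, where the covariance also fell, from 0.129 (0.070 simulated for unchanged groups) to 0.067 (0.00039 simulated). It was taken over probes called in M2 in place of either comparison, at 0.223.

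Distances moved with the filter; the cause was not tested. Without a filter and with the median filter they were 0.387 and 0.647 for M1 against M0, 0.0916 and 0.147 for M2 against M0, 0.432 and 0.726 for M1 against M2, 1.06 and 1.62 for CM-sM2 against M0, 1.04 and 1.61 against M2, and 1.45 and 2.26 against M1. Quantile normalization moved CM-sM2 against M0 to 1.23; the cause was not tested. With an array left out they ranged over 0.473 to 0.506, 0.107 to 0.128, 0.529 to 0.557, 1.23 to 1.38, 1.21 to 1.39 and 1.68 to 1.90, in that order.

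The 10 splits of 6 arrays into 3 and 3 are too few for a share under 0.05. The real split, 1 of 10, gave 26755, 5084 and 27284 calls, and the highest other split 3 in each comparison. Every other split mixes arrays of both states, which puts their real difference into the spread. Few calls there follow by construction and carry no weight.

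Averages over probes of a gene, gene lists and marker genes were not run, as probes have no gene names here. The separate tables hold the same values, so that alternative gives nothing new. Trend, block, treat and subset fits do not apply to CM-sM2. Signal over background limits dim probes.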

Other observations

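The test on opposed probes was added after the data were seen. Probes that moved in opposite directions in M1 and M2 were set beside CM-sM2. The 648 probes called higher in M2 and lower in M1 had a median log2 difference of 0.19 between CM-sM2 and M0 (0.07 to 0.26 over the 3 arrays), against -0.17 for matched uncalled probes. The 723 probes called lower in M2 and higher in M1 had a median of -0.52 (-0.65 to -0.47), against -0.17. In CM-sM2 54.9% of the 648 probes were above M0, where 40.3% of matched probes were. Of the 723 probes 63.1% were below M0, where 60.1% of matched probes were, so the share of this set barely differed. Both medians lay beyond all 10000 matched lists, on arrays that look normalized apart from M0, which is not a test. They share the M0 arrays with the calls, and were not recomputed with separate M0 arrays.

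The probes with the highest numbers were called more often. Of the 17485 filtered probes with the highest numbers, 48.5% were called in M1 against M0 and 12.6% in M2 against M0, compared with 23.2% and 3.66% of the other 78845 probes. Their median log2 signal was 7.88, against 5.08. A higher signal may make calls easier, so the shares were compared with other probes matched on mean signal. The ratio of shares went from 3.44 to 2.38 in M2 against M0, which argues against signal as the whole source there, and from 2.09 to 1.39 in M1 against M0, where the test does not decide. No biological explanation was tested, as the files do not say what these probe numbers stand for.

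In CM-sM2 the control probes of the glycolytic genes went apart. Human-GAPDH_3 and Human-GAPDH_5 were each higher than in M0 by 0.68, and Human-PGK1_3 and Human-PGK1_5 differed by -0.71 and -0.76, with the same directions after 75th percentile centring and quantile normalization. These scalings left the E1A control probes at medians of -0.857 and -0.867. The 9 E1A probes with a mean log2 signal above 5 differed by -1.15 to -0.35, a range that holds both PGK1 values. The lower PGK1 signal therefore cannot be told from a shift of these arrays. The GAPDH probes went the other way from the E1A probes, and no test was run.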
